A study of Drosophila melanogaster with 18 samples.

How the data were processed

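The series holds 18 libraries of 3′-end sequencing from testes of Drosophila melanogaster, in 9 groups of 2. Per the labels, control testes carried the driver bamGal4 alone, and the other testes had a spermatocyte knockdown, made with that driver, of 1 of 7 factors: PCF11, CstF64, CstF50, su(f), cbc, PABP2 or CPSF6. PCF11 was knocked down in 2 groups, PCF11_KD and PCF11_NIG_KD, with 2 RNAi lines. Per the labels' protocols, about 150 pairs of testes went into each library, crosses were kept for 3 days at 25 °C, and the progeny were moved to 29 °C until dissection. RNA was taken with the RNeasy Plus Mini kit and libraries were made with the Lexogen QuantSeq forward kit, which sequences the 3′ ends of polyadenylated transcripts. The labels state duplicates and do not say how far apart in time the duplicates or the groups were collected, nor whether duplicates came from separate crosses. They were treated as independent, and each SD, SE and p value rests on that.

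The authors counted reads with PolyA-miner, a program that compares the use of alternative poly(A) sites. Per the run logs, reads were assigned without regard to strand (setting 0) and without molecular identifiers (setting 0), to blocks of 30 nt at the 3′ ends of the authors' own list of 1098 sites, with no new sites added. Genes were kept at a minimum of 10 counts, sites at a minimum share of 0.05, and a further filter asked for at least 5 counts in a proportion of 0.6 of libraries; a beta-binomial test was used. Per the submitters' processing notes, Bowtie and SAMtools were used with the genome builds dm6 and BDGP6, without versions. The deposited count tables hold raw counts per site, unscaled, for 1082 sites in 529 gene entries with 522 symbols, of which 505 entries have 2 sites and 24 have 3. The authors' deposited result tables give, per gene, the mean fraction of counts at the proximal and at the distal site in control and knockdown (not used here), a score named PolyAIndex, and adjusted values in the unit p_value (p values of the beta-binomial test). Each of the 8 count tables pairs the controls with 1 knockdown group. The sites and the 2 control columns were identical in all 8, so the 18 libraries were joined in 1 table. The tables therefore cover genes with at least 2 sites on the authors' list. The name of the list sets bam against spermatocytes, and how its genes were chosen is not stated; if they were chosen for a switch of sites between early germ cells and spermatocytes, shares and numbers of changed genes here are not those of other genes. Changes in other genes were not analysed here.

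Symbols were looked up in the Ensembl annotation of BDGP6; 519 matched and 3 did not. Gene starts and ends in the authors' gene models were the same as in that annotation for 99.6% of the models matched by name. For each gene, the 2 sites with the most counts over all libraries were taken and called proximal and distal along the strand. The median distance between them was 415 nt, with quartiles of 218 and 734 nt. The proximal site lay in an annotated 3′ UTR in 509 genes, and the distal site in 293, with 219 distal sites downstream of the annotated gene end. Because counting was unstranded, genes with another annotated gene at a site were noted, 120 with one on the opposite strand and 42 with one on the same strand. Neither was found for 372 genes. Only annotated genes that covered the position of the site itself were seen in this way. Sequence motifs at the sites were not analysed here.

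Library totals in the count tables ran from 342763 to 819286 counts. For each gene the proximal share was the percent of the counts of both sites that fell on the proximal site, and values are means ± SD over n = 2 libraries. Where a site had no counts in a group, the upper limit is 3 counts of the group's total for that gene. Limits of this kind cover counting error only, since reads without molecular identifiers are not independent molecules.

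Changes in site usage were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, 2-sided). Each gene had 2 columns per library, 36 in all, with a coefficient for each library, so that the gene's level in a library cancelled and the tested term was the log2 odds of proximal against distal use. Negative log2 odds mean a move toward the distal site. Genes with a mean of at least 10 counts per library were tested, 525 in all. The fit over 18 libraries gave a common dispersion of 0.0316, and p values were adjusted by Benjamini and Hochberg within each comparison at a threshold of 0.05. Total counts per gene were tested in edgeR with TMM normalisation of library sizes and are given as log2 changes ± SE and as CPM (counts scaled to a common library size). Library sizes and TMM factors came from the genes on the authors' site list alone, so totals and CPM are relative to these genes. A change common to most of them would not be seen, and the scaling favours similar numbers of higher and lower totals. The 7 other knockdowns were also tested directly against PCF11_KD in the same fit; the 3 direct tests among CstF64_KD, CstF50_KD and suf_KD were added after the counts of changed genes had been seen. With 2 libraries against 2, an exact permutation test of a single value cannot go below a two-sided p of 0.333. Agreement between knockdowns was measured by Pearson's r over genes and by the overlap of calls. Beside them stand 50 simulations of unchanged groups that share the same controls. Such groups give almost no calls and lack the spread of real changes. Their overlap and r are therefore no full background for changed groups, and covariances are given beside r. Distances between sites were compared by 2-sided permutation tests with 100000 resamples.

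Before the data were examined, the tests, the alternatives, 16 gene lists and a rule for naming genes were set. The lists were cleavage and polyadenylation factors, translation and RNA-binding regulators, cell cycle and meiosis, the spermatocyte transcription program, germline stem cell and spermatogonia markers, post-meiotic spermatid genes, somatic markers of the testis, cytoskeleton and motors, membrane trafficking and autophagy, ubiquitin and proteasome, kinase, phosphatase and small GTPase signalling, chromatin and transcription, splicing with nuclear RNA processing and export, ribosomal proteins, mitochondrial proteins, and uncharacterised genes known by a CG or CR number. Lists with at least 5 tested members were compared with all other genes by a 2-sided Fisher's exact test on the share that moved toward distal, adjusted over 64 tests. The rule named, for PCF11_KD, PCF11_NIG_KD and cbc_KD, up to 15 genes toward distal and 10 toward proximal with the greatest change of share, past the threshold and with both knockdown libraries on the same side of both controls. It named up to 6 and 4 for each other knockdown, up to 5 genes with higher and 5 with lower totals, and in each list up to 4 members with the lowest adjusted p in PCF11_KD. Genes named outside this rule are said to be so.

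The pipeline was tested on simulated data with 200 changed genes of 525: edgeR called 39% of the changes of 1 and 83% of the changes of 2 on the log2 odds scale, 2 unchanged genes, and 0 with the wrong sign, and DESeq2 called 40% and 83%. The alternatives were DESeq2 1.42.0, edgeR's diffSpliceDGE over all sites (with limma 3.58.1), fits of 4 libraries alone, replicate number as a block, the most proximal site against all others, no count filter, a mean of at least 50 counts, a change of at least 10 points, DESeq2's size factors, the share of summed counts, and leaving out each library in turn. Leaving out genes with another annotated gene at a site, a 2-fold limit on totals, and the settings for the list, overlap, distance and all-8 results (usage and totals) were added after the data had been seen. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. The per-site statistics of the deposited tables were left out, since they repeat the counts of the sites that passed filters, and the authors' deposited result tables were used only for a comparison of calls.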

Results

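The data were counts of 3′-end reads at alternative poly(A) sites of 525 tested genes in testes of flies with bamGal4 alone or with a knockdown of a cleavage or polyadenylation factor in spermatocytes, 2 libraries per group. CstF64, CstF50 and su(f) are the subunits of the cleavage stimulation factor, PCF11 and cbc (the Clp1 homolog) form cleavage factor II, CPSF6 belongs to cleavage factor I, and PABP2 binds nuclear poly(A) tails. Totals per library ran from 342763 counts in control replicate 2 to 819286 in PCF11_NIG_KD replicate 1. The gene with most counts, CG33293, CG3982 or CG4686 depending on the library, took 2.92% to 5.9% of them. None of the listed cleavage and polyadenylation factors was among the genes measured (0 members), nor was any ribosomal protein gene (0 members), so the remaining level of each knocked-down factor was not measured. Shares below are the percent of a gene's counts at its proximal site, as mean ± SD of n = 2 libraries, and adjusted p values are from edgeR. The genes are those on the authors' own site list, whose name sets bam against spermatocytes. How it was made is not stated, so these genes need not be typical of genes with alternative sites. The labels give no collection or sequencing batch. Sample numbers in the column names recur in 4 pairs of groups, control with PABP2_KD, PCF11_KD with CPSF6_KD, suf_KD with CstF50_KD and PCF11_NIG_KD with CstF64_KD, so the libraries came from more than 1 sample sheet, and a sheet and a group cannot be told apart within a pair.

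In control testes the median gene had 77.4% ± 1.72 of its counts at the proximal site. The median fell to 62.8% ± 1.36 in PCF11_KD, 68.5% ± 0.365 in PCF11_NIG_KD and 47.3% ± 1.51 in cbc_KD, and was 71.6% ± 1.01 in suf_KD and 68.3% ± 4.47 in PABP2_KD. It was 78.1% ± 0.0112 in CstF64_KD, 84.1% ± 0.241 in CstF50_KD and 81.0% ± 1.42 in CPSF6_KD. Both knockdown libraries lay on one side of both controls in every knockdown but CstF64_KD, where the difference was within the spread of the controls; the exact permutation p was 0.333 for each other knockdown, the smallest this design allows, and 1 for CstF64_KD. The median over genes of the change in share was closer to 0 than the difference between medians in every knockdown but CstF64_KD. It was -6.24 points in PCF11_KD, -3.86 in PCF11_NIG_KD, -16.2 in cbc_KD, -1.69 in suf_KD, -2.62 in PABP2_KD, 1.07 in CstF64_KD, 3.73 in CstF50_KD and 2.08 in CPSF6_KD. With the share of counts summed over genes it was -13.0, -7.66, -27.6, -7.76 and -10.7 in the first 5 of these, and -3.04, of the other sign, in CstF64_KD. The smaller medians over genes depended on single libraries. Without control replicates 1 and 2 in turn they were -2.70 and -0.761 in suf_KD, -4.04 and -1.45 in PABP2_KD, 1.01 and 3.25 in CPSF6_KD, -0.0548 and 1.81 in CstF64_KD and -5.22 and -2.50 in PCF11_NIG_KD. Without PABP2_KD replicates 1 and 2 the value there was -0.947 and -4.66.

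**Figure D1:**
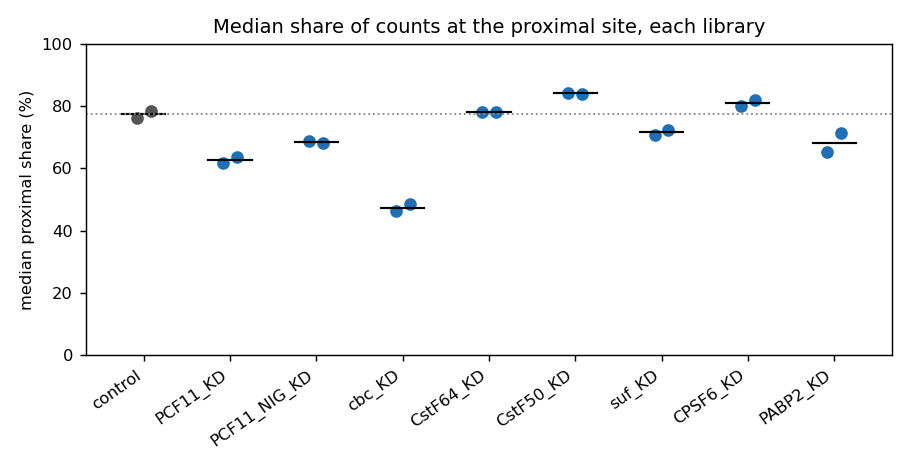
Median percent of counts at the proximal site over genes (vertical axis) in each library (points; bars are group means of n = 2, the dotted line is the control mean of 77.4%). Both cbc_KD libraries lie lowest, around a mean of 47.3%, and both CstF50_KD libraries highest, around 84.1%.

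PCF11_KD, against control, addressed which poly(A) sites change when PCF11 is depleted in spermatocytes. In 230 genes the use of the 2 sites moved toward the distal one, and in 50 toward the proximal one. isopeptidase-T-3, an older name whose identifier carries the current symbol Kpc2, fell from 95.8% ± 0.00738 proximal to 27.5% ± 1.45 (sites at 19672953 and 19673483 on chromosome 2R, BDGP6, log2 odds -5.92 ± 0.27, adjusted p = 1.01e-09). Cks30A, a subunit of cyclin-dependent kinase complexes, fell from 86.9% ± 0.877 to 19.7% ± 1.88 (9331672 and 9332027 on 2L, adjusted p = 9.33e-07). Mitofilin, which organises the inner mitochondrial membrane, fell from 82.2% ± 0.0293 to 20.1% ± 0.87 (22019665 and 22019505 on 3R, adjusted p = 3.52e-10).

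Others with the greatest moves toward distal in PCF11_KD were Trpm, a cation channel (97.5% ± 0.565 to 33.8% ± 3.77), Chd1, a chromatin remodeller (81.4% ± 12.2 to 18.5% ± 3.29), EMC1, of the endoplasmic reticulum membrane complex (74.7% ± 2.67 to 16.3% ± 0.978), Trc8, a ubiquitin ligase (77.2% ± 2.68 to 19.1% ± 1.67, with FipoQ on the opposite strand), and red (90.9% ± 1.16 to 35.5% ± 2.88). CG5065, CG9393, CG11357, CG11030 and CG5098 moved likewise; CG9393 fell from 91.2% ± 1.07 to 34.2% ± 1.13. Hr3, a nuclear receptor, and CG5776 had no distal counts in control, 0 of 26 and 0 of 13 counts over the group, which allows distal shares of up to 11.5% and 23.1%. Their proximal shares in PCF11_KD were 21.8% ± 10.7 and 27.4% ± 11.8. Toward the proximal site moved Mnn1, the menin homolog (22.7% ± 0 to 81.9% ± 12.1), Patr-1, a decapping activator (19.0% ± 6.73 to 68.9% ± 2.34), CG10089 (46.8% ± 1.85 to 91.0% ± 1.91), Cbl-PB, a ubiquitin ligase entry (28.3% ± 18.2 to 71.3% ± 2.34), IntS10, an Integrator subunit (18.3% ± 2.36 to 57.7% ± 8.33), Toll-7, a receptor (43.4% ± 4.76 to 81.0% ± 4.01), and X11L, an adaptor protein (55.2% ± 9.01 to 92.5% ± 4.46). Lrch-PC, CG1486 and the Tat entry did so too. The symbol Tat did not match the annotation there, and the entry lies at Atat. Mnn1, Patr-1 and CG10089 had means of only 22, 49 and 53.5 counts per control library. At such counts the SD of 0 of Mnn1 in control is no measure of precision. The call for CG1486 was lost without control replicate 1 (adjusted p = 0.0595).

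Among the lists, 10 of 13 cell cycle and meiosis genes moved toward distal in PCF11_KD, 1 toward proximal and 2 did not pass (10 and 1 adjusted over the list alone). mei-S332, which protects centromeric cohesion, fell from 60.6% ± 1.83 to 20.6% ± 0.703, fzr, an activator of the anaphase-promoting complex, from 94.0% ± 0.293 to 67.1% ± 2.79, the kinase gene Wee1 from 70.3% ± 7.28 to 39.1% ± 5.45 and the Greatwall kinase gene gwl from 42.7% ± 10.3 to 5.94% ± 4.64. That share of 76.9% compared with 43.0% of the other genes (Fisher's exact p = 0.0211, adjusted p = 0.193), so the list did not pass after adjustment. In kinase, phosphatase and small GTPase signalling, 2 of 16 moved toward distal and 5 toward proximal (the same numbers adjusted over the list alone), 12.5% against 44.8% toward distal (exact p = 0.0100, adjusted p = 0.184). The 5 included the adaptor gene drk (67.0% ± 0.488 to 88.4% ± 0.515) and Mnn1, whose product acts with histone methyltransferases. Of the uncharacterised genes, 74 of 141 moved toward distal and 3 toward proximal (74 and 3 adjusted over the list alone), 52.5% against 40.6% (exact p = 0.0173, adjusted p = 0.184).

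In chromatin and transcription 9 of 18 genes moved toward distal in PCF11_KD (9 adjusted over the list alone, 7 by DESeq2) and 0 toward proximal by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2), among them the TFIID subunit genes Taf7 (61.6% ± 0.224 to 45.0% ± 0.174) and Taf1 (95.2% ± 0.453 to 71.2% ± 8.16). Membrane trafficking had 7 of 15 toward distal, with the syntaxin genes Syx7 (43.0% ± 0.634 to 21.0% ± 0.604) and Syx6 (75.5% ± 2.54 to 30.1% ± 1.21), and 0 toward proximal by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2). Ubiquitin and proteasome had 5 of 11 toward distal. Among them were vih, the E2 enzyme of the anaphase-promoting complex (87.2% ± 1.1 to 32.2% ± 0.527), and the deubiquitinase gene Usp7 (24.2% ± 5.37 to 4.85% ± 0.245). Another annotated gene lay at a site of vih. The 1 toward proximal was ctrip (92.7% ± 0.00447 to 98.2% ± 0.623). Translation and RNA-binding regulators had 4 of 7 toward distal, among them the deadenylase gene twin (95.4% ± 0.241 to 78.4% ± 0.708) and orb, of the CPEB family (99.9% ± 0.0503 to 98.8% ± 0.0344), and 1 toward proximal, heph, a polypyrimidine-tract-binding protein gene (54.6% ± 3.79 to 78.5% ± 1.19). These 3 lists had the same numbers adjusted over the list alone. Toward distal moved 50% of the chromatin, 46.7% of the trafficking and 45.5% of the ubiquitin genes. Of the other genes 43.6%, 43.7% and 43.8% did so. For the translation list it was 57.1% against 43.6%. By edgeR, 0 of 5 cytoskeleton and motor genes passed, with Klp64D at 56.4% ± 19.2 and 23.9% ± 1.61 (adjusted p = 0.0892), and 0 of the 4 listed mitochondrial genes, which do not include Mitofilin, with Tom40 at 77.9% ± 0.532 and 74.95% ± 0.432; in both lists 0 had an unadjusted p under 0.05 and 0 passed by DESeq2.

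Of the short lists, the splicing genes Hrb98DE (72.1% ± 7.18 to 38.6% ± 4.25) moved toward distal and IntS10 toward proximal, and the spermatid gene nes fell from 79.9% ± 2.57 to 64.7% ± 2.82 while m-cup was at 98.7% ± 0.0298 and 98.8% ± 0.0849. chinmo, a transcription factor gene of early germ and cyst cells, fell from 81.0% ± 0.825 to 46.0% ± 2.21. Rbp9, zfh1 and simj, the other measured members of the spermatogonial, somatic and spermatocyte-program lists, did not pass (adjusted p = 0.225, 0.832 and 0.445). Over all 8 knockdowns, 0 of 64 list tests passed after adjustment, 8 had an unadjusted p under 0.05, and 0 passed with calls of DESeq2.

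Totals in PCF11_KD were higher in 124 genes and lower in 115. Cbl-PB rose by 3.07 ± 0.26 on the log2 scale, CG10089 by 2.42 ± 0.17, the centrosomin entry cnn-PD by 2.33 ± 0.28, and DUBAI and Nf1, a Ras regulator, by 1.88 each. Gprk2, a G-protein-coupled receptor kinase gene, changed by -2.92 ± 0.16 and Rbp9, an RNA-binding protein gene of the ELAV family, by -2.71 ± 0.23. The kinase gene Slik changed by -2.44 ± 0.24 and Trpm by -2.32 ± 0.34. In the same libraries zfh1, a marker of somatic cyst cells, changed by -1.74 ± 0.24, chinmo by 0.59 ± 0.15 and simj by 0.73 ± 0.21. The spermatid genes m-cup, r-cup and nes changed by -0.65 ± 0.14, 0.68 ± 0.17 and 0.07 ± 0.15. The lower total of dpr9 did not pass without control replicate 1 (adjusted p = 0.0697).

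PCF11_NIG_KD, a second RNAi line against PCF11, asked whether the changes recur with another knockdown of the same gene. Usage moved toward distal in 178 genes and toward proximal in 65. The greatest change was in the Dl entry, whose symbol did not match the annotation and which lies at Delta, the gene of a Notch ligand; it fell from 78.6% ± 0.244 to 5.55% ± 5.91 (adjusted p = 2.26e-06). Cks30A fell to 32.5% ± 4.57, isopeptidase-T-3 to 47.9% ± 0.515, Mitofilin to 37.4% ± 2.69, the mitochondrial calcium uniporter gene MCU from 84.9% ± 1.92 to 31.3% ± 2.29, the ubiquitin ligase gene dgrn from 74.0% ± 1.46 to 27.8% ± 4.22, and bbg from 65.3% ± 6.34 to 19.3% ± 0.0841. Mnn1 rose to 94.4% ± 2.62 proximal, CG10089 to 99.2% ± 0.724, Ephrin, a ligand of the Eph receptor, from 40.1% ± 8.42 to 89.3% ± 0.619, rut, an adenylyl cyclase gene, from 41.6% ± 20.1 to 89.0% ± 1.04, flfl, a phosphatase 4 subunit gene, from 45.4% ± 1.62 to 90.1% ± 4.81, and sbb from 15.2% ± 0.0466 to 66.3% ± 10.5.

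The 2 lines shared 161 genes toward distal, where independent lists would share 78.0. Simulated unchanged groups with the same controls shared 0, which says little, since groups without changes give almost no calls. Across genes, which are not independent replicates, r of the log2 odds changes was 0.780, and 0.582 in the simulations. The covariance was 2.404, against 0.2317 in the simulations. Directly tested, 119 genes differed, 101 of them with more proximal use in PCF11_NIG_KD, and in 63 of the 119 the share in PCF11_NIG_KD lay between control and PCF11_KD. Over all genes the median change of share was -6.24 points in PCF11_KD and -3.86 in PCF11_NIG_KD, the latter -2.50 without control replicate 2. Over the 230 genes toward distal in PCF11_KD it was -23.0 and -15.5; choosing them by PCF11_KD favours the larger change there. Named after their values were seen, flfl (90.1% against 47.1% in PCF11_KD) and Spt20, a subunit of the SAGA complex (98.3% ± 2.36 against 53.2% ± 0.147, control 62.5%), were more proximal in PCF11_NIG_KD, and Fs(2)Ket, the importin beta gene, more distal (29.3% ± 4.67 against 74.2% ± 1.66, control 67.8%). The number that differed was 76, 73 and 75 without PCF11_KD replicate 2, PCF11_NIG_KD replicate 1 and PCF11_NIG_KD replicate 2.

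In PCF11_NIG_KD 8 of 13 cell cycle genes moved toward distal (9 adjusted over the list alone, exact p = 0.0407, adjusted p = 0.326) and 1 of 16 signalling genes (1 adjusted over the list alone, exact p = 0.0154, adjusted p = 0.184). In chromatin and transcription 3 of 18 moved toward distal, 16.7% against 34.5% of the other genes, and 1 toward proximal. Adjusted over the list alone it was 0 in each direction by edgeR. It was 7 and 1 at an unadjusted p under 0.05, and 4 and 1 by DESeq2 over all genes. Totals were higher in 109 genes, with CG10089 at 1.96 ± 0.17 and the centriole gene spd-2 at 1.54 ± 0.14, and lower in 120, with HDAC4, a histone deacetylase gene, at -2.85 ± 0.32, Rbp9 at -2.71 ± 0.22 and gdl-ORF39 at -2.56 ± 0.21. The somatic marker zfh1 was at -1.91 ± 0.23 in these libraries, chinmo at -0.01 ± 0.15, simj at -0.01 ± 0.21 and m-cup at -0.44 ± 0.14.

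cbc_KD, against control, asked the same of the partner of PCF11 in cleavage factor II, and had the greatest number of changed genes of the 8 knockdowns, 318 toward distal and 35 toward proximal. isopeptidase-T-3 fell to 7.55% ± 1.45, Trpm to 12.8% ± 0.849, mrj, a co-chaperone gene, from 96.5% ± 0.334 to 13.1% ± 3.03, HtrA2, a mitochondrial protease gene, from 95.2% ± 0.406 to 19.2% ± 0.216, and ken, a transcriptional repressor gene, from 90.7% ± 0.01 to 14.3% ± 0.761. Cks30A fell to 11.7% ± 3.7, vih to 12.9% ± 1.01, red to 16.1% ± 1.96, app, a palmitoyltransferase gene, from 85.2% ± 1.08 to 12.4% ± 4.7, CG7841 from 96.0% ± 0.876 to 13.9% ± 0.0237 and CG5065 to 3.86% ± 0.452 (adjusted p = 1.15e-11). Mnn1 rose to 89.0% ± 3.75 proximal, Ephrin to 86.0% ± 2.58, rut to 87.1% ± 1.84 and heph to 90.3% ± 2.44. A fall of at least 30 points was seen in 184 genes in cbc_KD, 78 in PCF11_KD, 76 in PABP2_KD, 54 in PCF11_NIG_KD, 33 in suf_KD, 19 in CstF64_KD, 10 in CPSF6_KD and 3 in CstF50_KD.

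**Figure D2:**
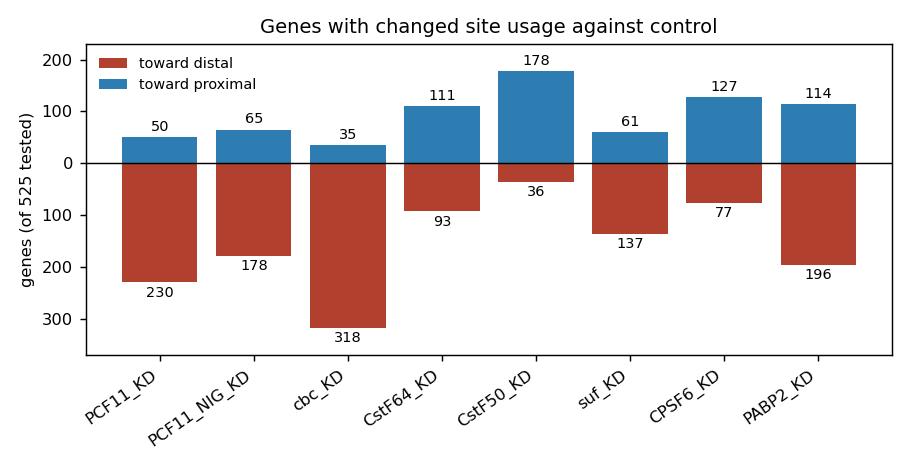
Number of the 525 tested genes whose usage moved toward the proximal site (upper bars) or the distal site (lower bars) in each knockdown against control. The numbers run from 318 toward distal and 35 toward proximal in cbc_KD to 36 and 178 in CstF50_KD.

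Of the genes toward distal, 215 were shared by cbc_KD and PCF11_KD, against 139 for independent lists. Across genes r was 0.812, and 0.530 in the simulations, with covariances of 3.268 and 0.2223. In the direct test 267 genes differed, 238 with more distal use in cbc_KD and 29 with less. Chosen after their values were seen, the kinesin gene Klp98A was at 34.0% ± 0.591 in cbc_KD, 91.9% ± 6.17 in PCF11_KD and 94.7% ± 1.87 in control, and PR-Set7, a histone methyltransferase gene, at 21.7% ± 3.93, 74.6% ± 1.95 and 87.6% ± 3.00. Ephrin was the reverse, at 86.0% ± 2.58 against 47.7% ± 0.0946. Mitochondrial genes moved toward distal in cbc_KD in 3 of 4 cases (3 adjusted over the list alone). Cytoskeleton genes did so in 3 of 5 (3). Of the other genes 60.5% and 60.6% moved toward distal. Cell cycle genes did so in 10 of 13 (10), 76.9% against 60.2% (Fisher's exact p = 0.264, adjusted p = 0.784). chinmo fell to 15.7% ± 1.13 proximal, simj, a gene set in the spermatocyte-program list that encodes a subunit of the NuRD complex and is no marker of spermatocytes, from 85.5% ± 1.01 to 57.6% ± 4.11, and zfh1 from 24.0% ± 2.73 to 6.74% ± 0.688.

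Totals in cbc_KD were higher in 171 genes and lower in 158. The Tat entry at Atat rose by 2.99 ± 0.15, cnn-PD by 2.96 ± 0.28, RtGEF by 2.89 ± 0.18 and gwl by 2.85 ± 0.21. axed changed by -3.93 ± 0.24, CG32161 by -3.89 ± 0.25 and HDAC4 by -3.57 ± 0.36. Among the listed genes, chinmo was at 1.56 ± 0.15, Rbp9 at -2.09 ± 0.22, zfh1 at -1.62 ± 0.23, simj at 0.73 ± 0.21, m-cup at -0.67 ± 0.14, r-cup at -0.24 ± 0.17 and nes at 0.62 ± 0.15.

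The distance between sites was compared with the calls. Genes toward distal in PCF11_KD had a median distance of 349.5 nt against 489 nt in the other genes (permutation p = 1e-05, the smallest the resampling can give, adjusted p = 2e-05), and in cbc_KD the medians were 396.5 and 450 nt (p = 0.181).

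**Figure D3:**
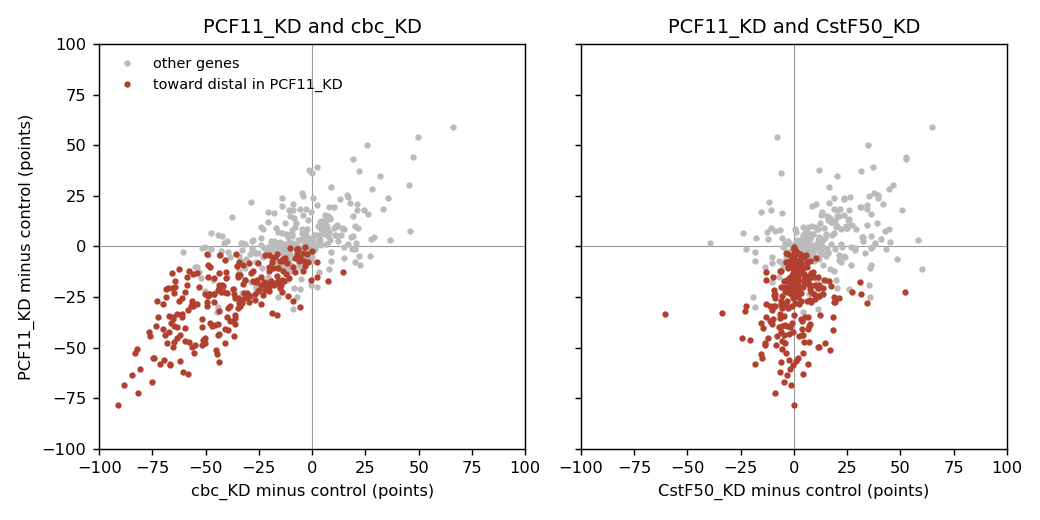
Change of the mean proximal share in percentage points of each gene in PCF11_KD (vertical axis) against cbc_KD (left) and CstF50_KD (right), with the 230 genes toward distal in PCF11_KD in red. The log2 odds changes had r = 0.812 with cbc_KD and 0.449 with CstF50_KD across genes. Simulated unchanged groups with the same controls had 0.530 and 0.523, so the second r lay below that background. Its covariance did not, at 1.137 against 0.2185. Of the red genes, 43 moved toward proximal in CstF50_KD, where independent lists would give 78.0, and 30 toward distal, where they would give 15.8.

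CstF50_KD, the knockdown of a subunit of the cleavage stimulation factor, moved 178 genes toward the proximal site and 36 toward distal. Ndf rose from 36.1% ± 1.65 to 94.2% ± 4.18 proximal and Cbl-PB to 80.7% ± 7.04. Mnn1 was at 87.5% ± 17.7, a call lost without CstF50_KD replicate 1 (adjusted p = 0.0983). Toward distal moved Dl (to 18.3% ± 4.61), Fs(2)Ket (67.8% ± 0.585 to 44.0% ± 3.65), pim, which encodes securin (62.2% ± 0.292 to 39.8% ± 3.11), and CG8195 (63.1% ± 5.69 to 42.4% ± 1.07). In signalling 10 of 16 genes moved toward proximal (12 adjusted over the list alone) and in ubiquitin and proteasome 7 of 11 (9). In chromatin and transcription it was 6 of 18 (6), in the cell cycle list 3 of 13 (3) and over all genes tested 178 of 525. The lists were not tested for moves toward proximal. By edgeR 0 of the signalling, chromatin and cell cycle genes moved toward distal (0, 0 and 2 at an unadjusted p under 0.05; 0 in each by DESeq2). The number changed was 128 without control replicate 1 and 132 with a minimum change of 10 points, against 214.

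Against PCF11_KD, 348 genes differed in CstF50_KD, 335 with more proximal use and 13 with less. Chosen after their values were seen, chb, a microtubule-binding CLASP gene, was at 79.8% ± 5.21 in CstF50_KD, 4.94% ± 0.388 in PCF11_KD and 27.7% ± 4.33 in control, and Chd1 at 85.8% ± 3.68, 18.5% ± 3.29 and 81.4% ± 12.2. Totals in CstF50_KD were higher in 95 genes, with CG10089 at 2.31 ± 0.17 and Su(var)3-3, a histone demethylase gene, at 1.86 ± 0.26, and lower in 92, with dpr9 at -4.70 ± 0.66, HDAC4 at -3.34 ± 0.36 and Rab5, of early endosomes, at -3.13 ± 0.28. Rbp9 was at -1.43 ± 0.21, zfh1 at -1.15 ± 0.23, chinmo at 0.17 ± 0.15 and simj at 0.02 ± 0.21. The number with changed totals was 114, 123 and 112 without control replicate 1, control replicate 2 and CstF50_KD replicate 1, against 187.

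CstF64_KD moved 93 genes toward distal and 111 toward proximal. CG43675 fell from 88.4% ± 0.468 to 40.7% ± 1.78, Ccdc85 from 75.4% ± 2.61 to 34.9% ± 2.83, CG9393 to 52.5% ± 0.0862 and Dl to 40.1% ± 0.808. siz, an Arf exchange factor gene, rose from 14.3% ± 4 to 73.2% ± 0.561, wts, the Hippo pathway kinase gene, from 19.8% ± 3.71 to 73.0% ± 6.36 and Patr-1 to 71.8% ± 2.68. Among uncharacterised genes 35 of 141 moved toward distal (35 adjusted over the list alone), 24.8% against 15.1% (exact p = 0.0138, adjusted p = 0.184). The number changed was 124 without CstF64_KD replicate 1, against 204. Against PCF11_KD, 250 genes differed, 240 with more proximal use. Totals were higher in 126 genes, with the G-protein gene Galphas at 3.17 ± 0.29 and cnn-PD at 3.05 ± 0.29, and lower in 124, with Gprk2 at -3.95 ± 0.17. Rbp9 was at -3.05 ± 0.23, zfh1 at -1.52 ± 0.24, simj at 1.34 ± 0.21, r-cup at 0.96 ± 0.17 and chinmo at 0.46 ± 0.15.

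suf_KD moved 137 genes toward distal and 61 toward proximal. CG42588 fell from 92.3% ± 10.9 to 37.6% ± 1.79, CG43675 to 42.0% ± 2.35, EMC1 to 32.3% ± 2.06, CG5098 from 73.4% ± 2.24 to 27.6% ± 5.46 and CG5065 to 42.4% ± 4.92. aPKC, a polarity kinase gene, rose from 19.1% ± 2.43 to 77.6% ± 5.75, siz to 70.2% ± 0.464, Patr-1 to 71.1% ± 3.4 and CG10089 to 98.1% ± 0.472. Of the uncharacterised genes 50 of 141 moved toward distal (50 adjusted over the list alone), 35.5% against 22.7% (exact p = 0.00362, adjusted p = 0.184). Against PCF11_KD 181 genes differed, 159 with more proximal use; the number was 118 and 119 without suf_KD replicates 1 and 2. Totals were higher in 133 genes, with cnn-PD at 3.39 ± 0.29 and Cbl-PB at 3.18 ± 0.26, and lower in 131, with Gprk2 at -3.44 ± 0.17 and PIG-L at -2.33 ± 0.17. Rbp9 was at -2.87 ± 0.23, zfh1 at -1.37 ± 0.23, simj at 1.47 ± 0.21, r-cup at 0.97 ± 0.17 and chinmo at 0.80 ± 0.15.

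The 3 subunits of the cleavage stimulation factor were compared directly, in tests added after the counts had been seen. Between suf_KD and CstF50_KD 255 genes differed, 239 with more distal use in suf_KD. The kinase gene fray was at 33.6% ± 1.65 and 91.0% ± 5 (control 59.2% ± 1.78) and acj6, a transcription factor gene, at 41.02% ± 0.736 and 88.9% ± 0.38 (control 77.4% ± 5.79). Between CstF64_KD and CstF50_KD 173 differed, 151 more distal in CstF64_KD, with CG43675 at 40.7% ± 1.78 and 96.1% ± 0.867. The number was 109 without CstF50_KD replicate 1 and 113 without CstF64_KD replicate 2. Between suf_KD and CstF64_KD 30 differed by edgeR, all more distal in suf_KD and 0 more proximal (125 at an unadjusted p under 0.05; 33 and 0 by DESeq2). Among them were red (57.2% ± 5.01 and 76.6% ± 0.648) and vih (46.3% ± 2.98 and 64.6% ± 1.18). That number was 7 and 10 without CstF64_KD replicates 1 and 2, and 9 and 17 without suf_KD replicates 1 and 2. These genes were chosen after their values were seen. CstF64_KD and suf_KD shared 93 genes toward distal, against 24.3 for independent lists. Across genes r was 0.908, and 0.547 in the simulations, with covariances of 2.359 and 0.2254. For CstF50_KD and suf_KD r was 0.50 and 0.534, but the covariance was 1.152 against 0.224 in the simulations. They shared 30 genes toward distal and 49 toward proximal, against 9.39 and 20.7 for independent lists.

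CPSF6_KD, in cleavage factor I, moved 77 genes toward distal and 127 toward proximal. Dl fell to 7.83% ± 4.64, pim to 25.0% ± 1.8 and CG5098 to 34.5% ± 1.34. CG10089 rose to 99.2% ± 0.303, CG6983 from 36.1% ± 3.07 to 85.4% ± 1.95, sbb to 64.5% ± 0.645 and flfl to 94.5% ± 7.71. The fall of HDAC4 to 27.1% ± 20.6 did not pass without CPSF6_KD replicate 2 (adjusted p = 0.133). In chromatin and transcription 7 of 18 genes moved toward proximal (7 adjusted over the list alone) and 1 toward distal. Over all genes tested 127 of 525 moved toward proximal. The number changed was 134 without control replicate 1 and 129 without CPSF6_KD replicate 2, against 204.

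Against PCF11_KD 310 genes differed in CPSF6_KD, 293 with more proximal use; chosen after its values were seen, Hsc70-5, a mitochondrial chaperone gene, was at 77.1% ± 4.14 against 19.0% ± 0.00231. Totals in CPSF6_KD were higher in 108 genes, with Cbl-PB at 2.73 ± 0.27 and the Wnt effector gene pan at 1.96 ± 0.37, and lower in 89, with Rbp9 at -3.32 ± 0.24 and E(bx)-PC, of the NURF remodelling complex, at -2.56 ± 0.46. zfh1 was at -1.89 ± 0.25, m-cup at 0.64 ± 0.14, chinmo at 0.08 ± 0.15 and simj at -0.03 ± 0.21. The number with changed totals was 131 without control replicate 1, against 197.

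PABP2_KD moved 196 genes toward distal and 114 toward proximal. dock, an adaptor protein gene, fell from 89.9% ± 5.05 to 17.3% ± 6.5, Mitofilin to 16.6% ± 1.38, Deaf1, a transcription factor gene, from 89.3% ± 1.89 to 25.0% ± 19.6, isopeptidase-T-3 to 32.8% ± 7.81 and CG5098 to 9.93% ± 3.72. siz rose to 79.8% ± 20.8, Cbl-PB to 88.9% ± 1.48 and the autophagy gene Atg18b from 11.6% ± 1.22 to 66.5% ± 8.85. By edgeR 3 of 3 spermatid genes moved toward distal (3 adjusted over the list alone, 2 by DESeq2), with nes at 48.2% ± 7.28 against 79.9% ± 2.57, and 8 of 16 signalling genes moved toward proximal and 1 toward distal (8 and 1 adjusted over the list alone; 6.25% against 38.3% toward distal, exact p = 0.00756, adjusted p = 0.184). Of the genes outside the spermatid list 37.0% moved toward distal, and over all genes tested 114 of 525 moved toward proximal. The 2 libraries differed more than in any other knockdown (medians of 65.1% and 71.4%). A fit of the 2 control and 2 PABP2_KD libraries alone called 167 genes, against 310.

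Against PCF11_KD 200 genes differed in PABP2_KD, 57 with more distal and 143 with more proximal use; chosen after its values were seen, DUBAI was at 30.01% ± 12.8 against 73.0% ± 4.44. Totals in PABP2_KD were higher in 171 genes, with CG12219 at 2.80 ± 0.24 and xmas, an mRNA export gene, at 2.77 ± 0.27, and lower in 155, with orb2, a CPEB family gene, at -3.87 ± 0.36, the mitochondrial ribosomal gene mRpS5 at -3.70 ± 0.35 and Rab5 at -3.11 ± 0.27. Rbp9 was at -2.31 ± 0.22, zfh1 at -2.39 ± 0.24, m-cup at -1.06 ± 0.15, chinmo at 0.58 ± 0.15, nes at 0.50 ± 0.15 and simj at 0.44 ± 0.21. The fit of 4 libraries alone called 206 changed totals, against 326.

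Over the 8 knockdowns, 476 of the 525 genes changed usage in at least 1 and 49 in none. All 8 moved 19 genes toward distal, where independent lists would share 0.0082, and 6 toward proximal, with 0.000181 for independent lists. The 19 included pim, from 62.2% ± 0.292 in control to between 5.53% in cbc_KD and 39.8% in CstF50_KD. Others were vih, from 87.2% ± 1.1 to between 12.9% and 72.2%, Mitofilin, mrj, Trpm, Trc8 and Dl. The smallest moves of some were slight. Trpm went from 97.5% to 95.2% in CPSF6_KD, mrj from 96.5% to 92.9% in CstF50_KD and CG6218 from 99.9% to 99.6% in PCF11_NIG_KD. Another annotated gene lay at a site of vih and at a site of Trc8. The 6 were CG10089, Csk, a Src-inhibiting kinase gene, Mnn1, Patr-1, X11L and rut. Mnn1, Patr-1 and CG10089 had means of only 22, 49 and 53.5 counts per control library. The call for Mnn1 in CstF50_KD was lost without CstF50_KD replicate 1 (adjusted p = 0.0983) and that for Patr-1 in PABP2_KD in the fit of 4 libraries (adjusted p = 0.0513). Without control replicate 2 the numbers were 10 and 5, without control replicate 1 they were 17 and 3, and with DESeq2 15 and 5. In the authors' deposited tables, per gene, 273 genes lengthened and 92 shortened in PCF11_KD, 354 and 62 in cbc_KD, and 61 and 225 in CstF50_KD. Among genes called both there and here, at most 2 in each of the 8 knockdowns had the opposite direction. Between 39 (PABP2_KD) and 136 (CstF64_KD) genes per knockdown were called by the authors alone. Both sets of calls rest on the same counts.

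**Figure D4:**
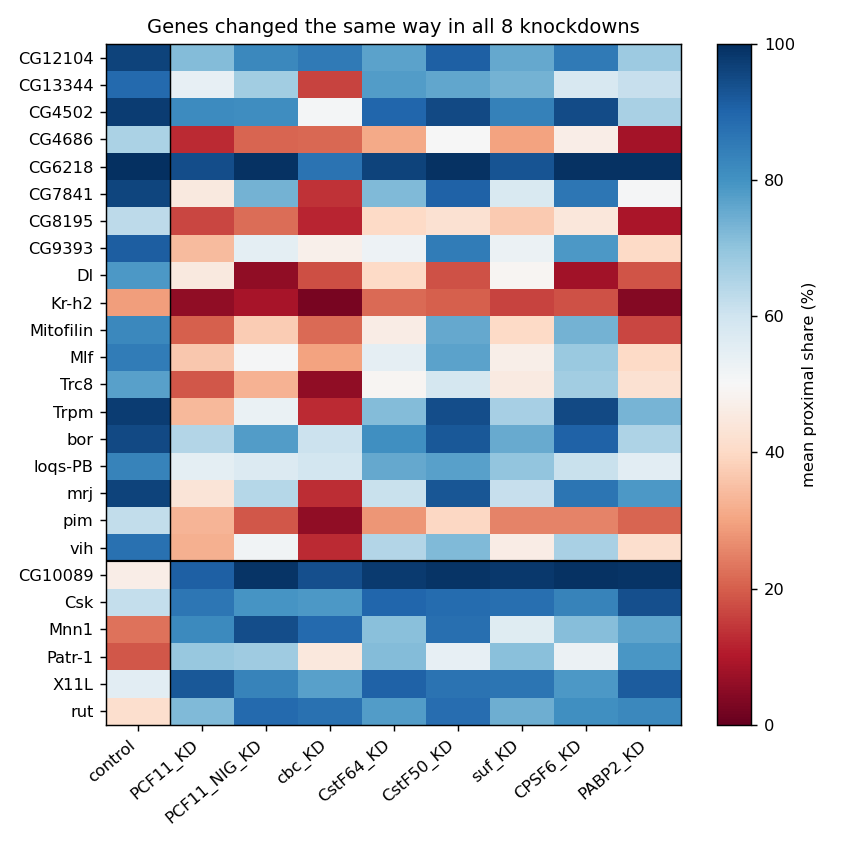
Mean percent of counts at the proximal site (colour) in control and each knockdown for the 25 genes that moved the same way in all 8, with the 19 toward distal above the line and the 6 toward proximal below it. pim runs from 62.2% in control to 5.53% in cbc_KD, and CG10089 from 46.8% to 99.2% in CPSF6_KD.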

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

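The sample-sheet, overlapping-gene and direct tests on genes shared by all 8 knockdowns were set before their results were seen. Chosen only after the result was seen were the tests of control libraries for PCF11_KD, of fewer spermatocytes and of more early germ cells. The same holds for the tests of another tissue and of single control libraries, and for the direct tests between CstF subunits.

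Knockdowns of subunits of one complex differed. By direct edgeR test 255 genes differed between suf_KD and CstF50_KD (239 more distal in suf_KD), 173 between CstF64_KD and CstF50_KD (151 more distal in CstF64_KD) and 30 between suf_KD and CstF64_KD (30 more distal in suf_KD, with 125 at an unadjusted p under 0.05; 7 to 17 when 1 of the 4 libraries was left out, lowest without CstF64_KD replicate 1). Reads of annotated genes that cover a site are argued against as the source for suf_KD and CstF50_KD. Of the called genes without another annotated gene at either site, 93.5% were more distal in suf_KD. The suf_KD minus CstF50_KD changes had r = 0.0351 across genes with those of PABP2_KD minus control, so they did not recur there. With PCF11_KD minus CPSF6_KD and PCF11_NIG_KD minus CstF64_KD, the other pairs that share sample numbers, r was 0.571 and -0.479. Which group of a pair lay on which sheet is not stated, so the order of subtraction and the sign of r are arbitrary. Each pair also differs by knockdown, so these values cannot decide on a difference between sample sheets. The number of sheets is not stated, and a sheet effect cannot be excluded. A different depth of each knockdown, or different roles of the subunits, may account for the split and were not tested.

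Cleavage factor II and the distal shift. Direct tests against PCF11_KD found 267 genes for cbc_KD (238 more distal), 119 for PCF11_NIG_KD (101 more proximal), 348 for CstF50_KD (335 more proximal), 310 for CPSF6_KD (293 more proximal), 250 for CstF64_KD (240 more proximal), 200 for PABP2_KD (143 more proximal) and 181 for suf_KD (159 more proximal). Reads of annotated genes that cover a site are argued against as the cause of the move against control. Where no such gene lay at a site, 81.6% of called genes were toward distal in PCF11_KD and 88.1% in cbc_KD. Reads from unannotated extensions of neighbouring genes were not covered and stay open. Unusual control libraries are not excluded. Without the controls, 335 genes were more distal in PCF11_KD than in CstF50_KD, so the 2 knockdowns differed. Which of them moved cannot be told from that, since CstF50_KD itself moved 178 genes toward proximal against control. cbc_KD was not tested against CstF50_KD. Groups that share sample numbers came from different sample sheets. Among these, median proximal shares were 62.8% in PCF11_KD against 81.0% in CPSF6_KD and 68.5% in PCF11_NIG_KD against 78.1% in CstF64_KD. They were 71.6% in suf_KD against 84.1% in CstF50_KD and 68.3% in PABP2_KD against 77.4% in control. An effect of the sheet on the distal shift is therefore not excluded. Over the genes toward distal, CPM (scaled counts) at the proximal site changed by a median log2 of -0.64 in PCF11_KD and -1.34 in cbc_KD, and at the distal site by 1.497 and 1.70. CPM and totals are relative to the genes on the site list, so a change common to these genes would not be seen. Fewer spermatocytes would raise markers of all other cell types. The log2 total change of Rbp9, of early germ cells, was -2.71 ± 0.23 in PCF11_KD and -2.09 ± 0.22 in cbc_KD, that of the somatic gene zfh1 -1.74 and -1.62, and that of chinmo 0.59 and 1.56. Since Rbp9 and zfh1 were lower in all 8 knockdowns, their fall cannot be told apart from a difference of the controls, and fewer spermatocytes, like a gain of early germ cells that express chinmo, stay open. The genes come from a site list named for bam against spermatocytes, which leaves a change of cell types harder to set aside. The proximal-site median minus the change of m-cup, the lowest of the 3 measured spermatid genes, was 0.006 in PCF11_KD and -0.67 in cbc_KD. Bootstrap intervals, drawn over the genes toward distal only, were -0.19 to 0.12 and -0.93 to -0.41. They hold neither the spread between libraries nor the error of m-cup, and the values do not decide. The other spermatid genes did not follow m-cup, with r-cup at 0.68 and -0.24 and nes at 0.07 and 0.62. A direct effect of cleavage factor II on site choice stays open beside it.

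Genes changed the same way in all 8 knockdowns. The 19 toward distal, such as pim, vih and Mitofilin, and the 6 toward proximal exceed the 0.0082 and 0.000181 that independent lists would share, and all 8 were compared with the same 2 controls. A chance deviation of a single control library is argued against as the source of all of them. Control replicate 1 was set as the only control of 4 knockdowns and replicate 2 of the other 4. Over the 70 ways to divide the knockdowns, between 12 and 19 genes still moved the same way in all 8. Independent lists would share at most 0.00172. Toward distal it was 10 to 16 genes and toward proximal 2 to 4. For part of the 19 and part of the 6 such a deviation therefore stays open. A deviation that both controls share stays open: 23 of the 25 differed between PCF11_KD and another knockdown in at least 1 direct test, but so did 469 of all 525 genes, and a difference between knockdowns does not bear on a shift common to them. RNA of another tissue in the controls, which would add distal counts and leave the proximal site alone, also stays open, since over the 6 genes the median log2 change was 0.859 at the proximal site, from 0.10 in rut to 3.19 in CG10089, and -1.97 at the distal site. A common response of the tissue to the loss of any of these factors was not tested and stays open.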

How the results depend on the processing

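The 2-fold limit on totals, the settings without overlapping genes and those for usage and totals shared by all 8 knockdowns were chosen only after the results were seen. No call of a named gene was reversed in direction. For numbers of changed genes only the sum of both directions was compared, so a reversal was not scored. The median change of share in CstF64_KD took the other sign with summed counts and without control replicate 1. DESeq2, the replicate block, no count filter and a mean of at least 50 counts kept the number of changed genes per comparison within 1.5 times. So did the most proximal site against the rest, diffSpliceDGE and DESeq2's size factors, where they were run. Counts within a gene list could move more. By DESeq2 1 signalling gene moved toward distal in PCF11_KD, against 2, and 2 translation genes toward proximal in CPSF6_KD, against 4. Replicate numbers did not pair the samples (median r 0.0351 over 36 pairs of groups, 10 above 0.1), so the replicate block is one setting among the others. Of the named genes, 154 site usage and 80 total calls, 2 were lost in fits of 4 libraries and 1 with diffSpliceDGE, and leaving out 1 library lost 38 of 616 and 3 of 320 usage and total calls. At this depth and with 2 libraries per group, simulated log2 changes of 1 were called in 39% of cases; depth was not varied on its own. Leaving a library out leaves 1 in its group, which is then assumed to vary like the others.

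Leaving out 1 library gave 124 to 167 changed genes in CstF64_KD, 128 to 168 in CstF50_KD and 129 to 160 in CPSF6_KD for usage, and 112 to 145 in CstF50_KD and 131 to 166 in CPSF6_KD for totals. The same in the direct tests gave 73 to 86 for PCF11_NIG_KD and 118 to 131 for suf_KD against PCF11_KD, 7 to 17 for suf_KD against CstF64_KD and 109 to 133 for CstF64_KD against CstF50_KD. The 25 genes changed the same way in all 8 knockdowns became 15 to 26, lowest without control replicate 2, and 18 to 30 in the other settings. The 39 genes with totals lower or higher in all 8 became 21 to 39, lowest without control replicate 1, and 36 to 43 in the other settings. Fewer libraries in the fit are the construction of these settings. A minimum change of 10 points, a higher threshold by construction, left 132 genes in CstF50_KD. In PABP2_KD, fits of 4 libraries gave 167 for usage and 206 for totals; the cause was not tested beyond the wider spread of these libraries. A 2-fold limit, also a higher threshold, left 107 totals in PCF11_KD, 101 in PCF11_NIG_KD, 191 in cbc_KD, 113 in CstF64_KD, 73 in CstF50_KD, 109 in suf_KD, 77 in CPSF6_KD and 173 in PABP2_KD.

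The median change of the proximal share over genes was -6.24 points in PCF11_KD, -3.86 in PCF11_NIG_KD, -16.2 in cbc_KD, 1.07 in CstF64_KD, 3.73 in CstF50_KD, -1.69 in suf_KD, 2.08 in CPSF6_KD and -2.62 in PABP2_KD. With the share of summed counts it was -13.0, -7.66, -27.6, -3.04, -7.76 and -10.7 in PCF11_KD, PCF11_NIG_KD, cbc_KD, CstF64_KD, suf_KD and PABP2_KD, with the other sign in CstF64_KD; the cause was not tested. Leaving out 1 library gave -5.22 to -2.50 in PCF11_NIG_KD, -18.0 to -15.4 in cbc_KD and 2.53 to 4.98 in CstF50_KD. Without overlapping genes the difference in distance between sites in PCF11_KD was -204.5 nt, against -139.5; the cause was not tested. The list tests gave 0 past the threshold in each setting, with lowest adjusted p values of 0.106 (DESeq2), 0.157 (replicate block), 0.167 (no filter), 0.226 (at least 50 counts) and 0.263 (without overlapping genes), and 0.184 in the reported fit.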

Other observations

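The comparisons of totals across knockdowns, of site location, and of the genes shared by all 8 were chosen only after the results were seen, while the test of totals against distal use was set before. Total counts of 18 genes were lower in all 8 knockdowns, where independent lists would share 0.00409, and of 21 genes higher, where they would share 0.00618. The comparisons share the same 2 control libraries, so independent lists are no full background. The numbers were 11 and 10 without control replicate 1, 12 and 13 without control replicate 2, 12 lower without PCF11_KD replicate 2 and 12 higher without CstF50_KD replicate 1. With each control library as the only control of 4 knockdowns they were 9 to 13 and 8 to 12 over the 70 ways to divide them. A difference that both controls share was not excluded. Named after their values were seen, the lower ones included the spermatogonial gene Rbp9 (log2 -3.32 to -1.43) and the somatic gene zfh1 (-2.39 to -1.15). Others of them were the G-protein-coupled receptor kinase gene Gprk2 (-3.95 to -1.35), the histone methyltransferase gene PR-Set7 (-2.15 to -0.97) and Rab5 (-3.13 to -0.65). The higher ones included cnn-PD (1.35 to 3.39), spd-2 (0.92 to 2.29), CycA (0.75 to 2.02), mei-218 (1.03 to 1.61) and Taf1 (0.72 to 1.30). These lists of genes were not tested for a theme.

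Distal sites downstream of the annotated gene end were compared with those in annotated 3′ UTRs. In cbc_KD 152 of 218 genes of the first kind moved toward distal (69.7%), against 157 of 291 of the second (Fisher's exact p = 0.000343, adjusted over 8 knockdowns p = 0.00275). In PABP2_KD the percentages were 45.4% and 31.3% (exact p = 0.0012, adjusted p = 0.00482), and in PCF11_KD 49.1% and 39.5% (exact p = 0.0377, adjusted p = 0.0532). They had the same order in the other knockdowns, at 39.0% and 30.2% in PCF11_NIG_KD and 21.6% and 14.1% in CstF64_KD. They were 30.3% and 22.0% in suf_KD, 18.8% and 11.3% in CPSF6_KD and 8.72% and 5.15% in CstF50_KD. Adjusted p values of the exact tests there ran from 0.0532 to 0.150. All 8 comparisons share the same controls.

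One hypothesis was that genes that moved toward the distal site had fewer transcripts, since a longer 3′ UTR can hold more sites for repressors. Median log2 total changes of the genes toward distal differed from those of the other genes by 0.22 in PCF11_KD (permutation p = 0.0299, adjusted p = 0.239), 0.085 in PCF11_NIG_KD (p = 0.212, adjusted p = 0.458) and -0.11 in cbc_KD (p = 0.229, adjusted p = 0.458). None passed after adjustment, the differences had both signs, and the hypothesis stays undecided.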
